A study of Mus musculus with 4 samples.

How the data were processed

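RNA was prepared from cultured aortic medial smooth muscle cells of wild-type male C57Bl/6 mice. Per the labels' protocols, cells were released from the aortic media with collagenase and elastase, passaged 3 to 5 times, and lysed for RNA with integrity numbers of 7.8 to 9. Libraries were made from total RNA with a strand-preserving poly(A) kit (TruSeq Stranded mRNA), per the labels' protocols. Trim Galore, cutadapt, TopHat and the mouse build GRCm38 are named in the submitters' processing notes, without versions. The counting tool, its annotation and its strand setting are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical paralogs may be divided differently from their origin.

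The authors deposited 1 table of log2 values for 25965 genes in 4 libraries, with the position of each gene. From the values, each is the log2 of a whole number of reads times a constant of its library, with no division by gene length. Genes without reads carry a floor of 0.9 read. Whole reads were recovered by dividing by the value of 1 read (0.0344, 0.0346, 0.0455 and 0.0340 in libraries 1 to 4), and 99.8%, 99.8%, 99.8% and 99.7% of values came out within 0.05 read of a whole number. The recovered reads on genes were 56265771, 55521915, 40342561 and 56793195. The table's values on a linear scale sum to 1935437, 1920745, 1834291 and 1932623 in libraries 1 to 4, so they are not CPM of the reads on genes. The constants match totals of 29071351, 28906437, 21993547 and 29386587, so the recovered reads were 1.94, 1.92, 1.83 and 1.93 times these totals. The reads of a pair, or the parts of a spliced read, may thus have been counted separately, and the sources do not say. Among genes with 1 to 20 recovered reads, 45.3%, 47.5%, 50.1% and 47.3% had an even number, without the excess that separate counting of both reads of a pair in a gene would give. What was counted stayed open, and read counts, thresholds in reads and intervals are in these recovered units. In libraries 1 to 4, 8421, 9070, 10801 and 9957 genes had no reads. A count of 0 allows up to 3 reads, and this floor and all intervals cover counting error only, because reads without molecular identifiers are not independent molecules. Mitochondrial genes took 0.0653%, 0.133%, 0.382% and 0.113% of the reads, and the 100 highest genes 27.5%, 28.2%, 34.1% and 33.1%.

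The columns carry the library names of the labels, and all 4 were assigned to the only group, so no comparison between groups was made. Tests, 29 gene lists (460 distinct genes), 22 contrasts, the rule for named genes and the alternatives were fixed before the data were examined, and later additions are named as such. The rule chose the 15 genes with the highest mean, the 4 highest genes and the first 3 listed genes of each list, the genes of the contrasts, the 15 most variable detected genes with a mean of at least 4 times the threshold (log2 of 2), each detected Hox gene, and 5 sex-linked genes. This gave 208 genes, of which a few are not reported here. Numbered gene models, mitochondrial and RNA genes were left out of the rankings. Older symbols were matched for genes renamed since, and 1 of 471 list entries (Kmt2a) was not found.

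Detection required a log2 value of at least 0 in 4 of 4 libraries. The level of a list was the median of its measured genes in each library, with the mean and SD over libraries and the percentile of its median among 10000 random lists of the same size from genes detected in at least 1 library. Differences within libraries were tested with an exact two-sided sign-flip permutation test (16 sign arrangements), with Benjamini-Hochberg adjustment over 22 contrasts. A gene was called variable with an SD above 0.5 between libraries. Differences of a list between libraries were described by the SD of its mean over detected genes, with its percentile among 10000 random lists matched on 20 expression bins, for lists with at least 5 detected genes. Percentiles describe these libraries and are not tests. A planned conversion of counts to CPM and a pseudocount were not needed for values already on the log2 scale.

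The alternatives were other detection thresholds, median-ratio size factors, list means in place of medians, random lists from all genes, levels divided by exon length, no filter on low values, an SD above 1, 10 expression bins, and leaving out each library. Added after the data were seen were a chi-square test of the recovered reads against Poisson sampling, a correction for exon length and GC content, and genes without reads at 3 reads. Exon lengths and GC content came from GENCODE M21 on GRCm38, matched for 93.2% of genes. Of genes matched by symbol and overlapping position, 58.6% had identical start and end, so the authors' annotation was another version, and printed coordinates are those of the deposited table. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. On simulated reads with the means and depths of these libraries (13138 genes), 100 of 100 genes changed by 4-fold and 100 of 100 changed by 8-fold had an SD above 0.5, as did 1 of 12916 unchanged genes. Each changed gene was changed in a single library, so an SD above 0.5 followed from the size of the change. Unchanged genes varied by counting error only, so their share is not an error rate for these libraries.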

Results

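Polyadenylated RNA was sequenced in 4 libraries of vascular smooth muscle cells (VSMCs), the contractile cells of the arterial wall. The cells came from the aortic media of wild-type male C57Bl/6 mice aged 8 to 14 weeks and had been grown in serum-containing medium for 3 to 5 passages. All 4 libraries belonged to 1 group, so the measurements were the level of each gene in cultured cells, differences between genes within a library, and differences between libraries of the same kind. The libraries held 56265771, 55521915, 40342561 and 56793195 reads on genes in libraries 1 to 4, as recovered from the table, and a sequenced fragment may be counted more than once in them. A gene counted as detected when its scaled read count was at least 1 (log2 of 0) in 4 of 4 libraries, which took 30, 29, 22 and 30 reads. By this measure 12306 of 25965 genes were detected (47.4%), and 14178 reached the threshold in at least 1 library. Levels below are log2 scaled read counts, given as mean ± SD over the libraries (n = 4). They were not divided by transcript length, so differences between genes compare reads and not molecules.

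Vim, the mesenchymal intermediate filament gene, had the highest mean of the ranked genes at 14.03 ± 0.19 (chromosome 2, 13573927 to 13582826, GRCm38), and Col1a1, a chain of the fibrillar type I collagen, followed at 14.01 ± 0.33 (chromosome 11, 94936224 to 94953042). Eln, encoding the elastin of elastic fibres, averaged 13.80 ± 1.33 (chromosome 5, 134703781 to 134747241), with single values as deposited of 13.01, 12.35, 14.70 and 15.13. Col2a1, encoding the main fibrillar collagen of cartilage, ranked sixth at 13.60 ± 0.51 (chromosome 15, 97975602 to 98004695). The other genes among the 15 highest were S100a6 (13.86 ± 0.39), Ctsd (13.68 ± 0.28), Fn1 (13.53 ± 0.63), Rpl13a (13.44 ± 0.49), Myh9 (13.36 ± 0.30), Col5a2 (13.26 ± 0.47), Myl6 (13.19 ± 0.77), Col1a2 (13.15 ± 0.52), S100a4 (13.04 ± 0.26), Actb (13.03 ± 1.03) and Lgals1 (13.02 ± 0.39). Mitochondrial transcripts, numbered gene models and RNA genes were left out of this ranking.

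Contractile genes were highly expressed on average over the libraries. Of 24 measured genes of the contractile apparatus, 21 were detected, and the list's median was 6.95 ± 1.11, above all 10000 random lists of the same size (percentile 100). The medians in libraries 1 to 4 were 7.08, 5.35, 7.53 and 7.84. In library 2 this was near 5.22, the median of all detected genes in that library. Acta2, the smooth muscle actin gene, averaged 12.18 ± 1.05 (chromosome 19, 34241090 to 34255336), Tagln 11.48 ± 0.71, Tpm2 12.91 ± 0.92 and Tpm1 12.01 ± 0.83. Myh11, the smooth muscle myosin heavy chain gene often used as the most specific marker of the lineage, was lower at 7.44 ± 1.65 (chromosome 16, 14194527 to 14291408). Pln, encoding the sarcoplasmic calcium pump regulator phospholamban, had no reads in 4 of 4 libraries, which allows up to 3 reads in each.

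Of 20 transcription factor genes that regulate smooth muscle genes, 16 were detected, with a list median of 5.17 ± 0.42 (percentile 76.5). The other 4 were Myocd, the cardiac and smooth muscle coactivator of Srf, and Klf5, Meox2 and Tcf21, named after their values were seen. Srf averaged 7.01 ± 0.82, its coactivator Mkl1 6.17 ± 0.30, Prrx1 7.87 ± 0.12, and the Hippo pathway genes Tead1 and Wwtr1 7.26 ± 0.64 and 7.15 ± 0.41. Myocd had 51, 14, 12 and 53 reads, a level of -0.06 ± 1.04. Klf4, a zinc finger factor linked to loss of the contractile phenotype, averaged 4.77 ± 0.55, and exceeded Myocd by 4.84 ± 0.87 log2 units in 4 of 4 libraries.

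**Figure D1:**
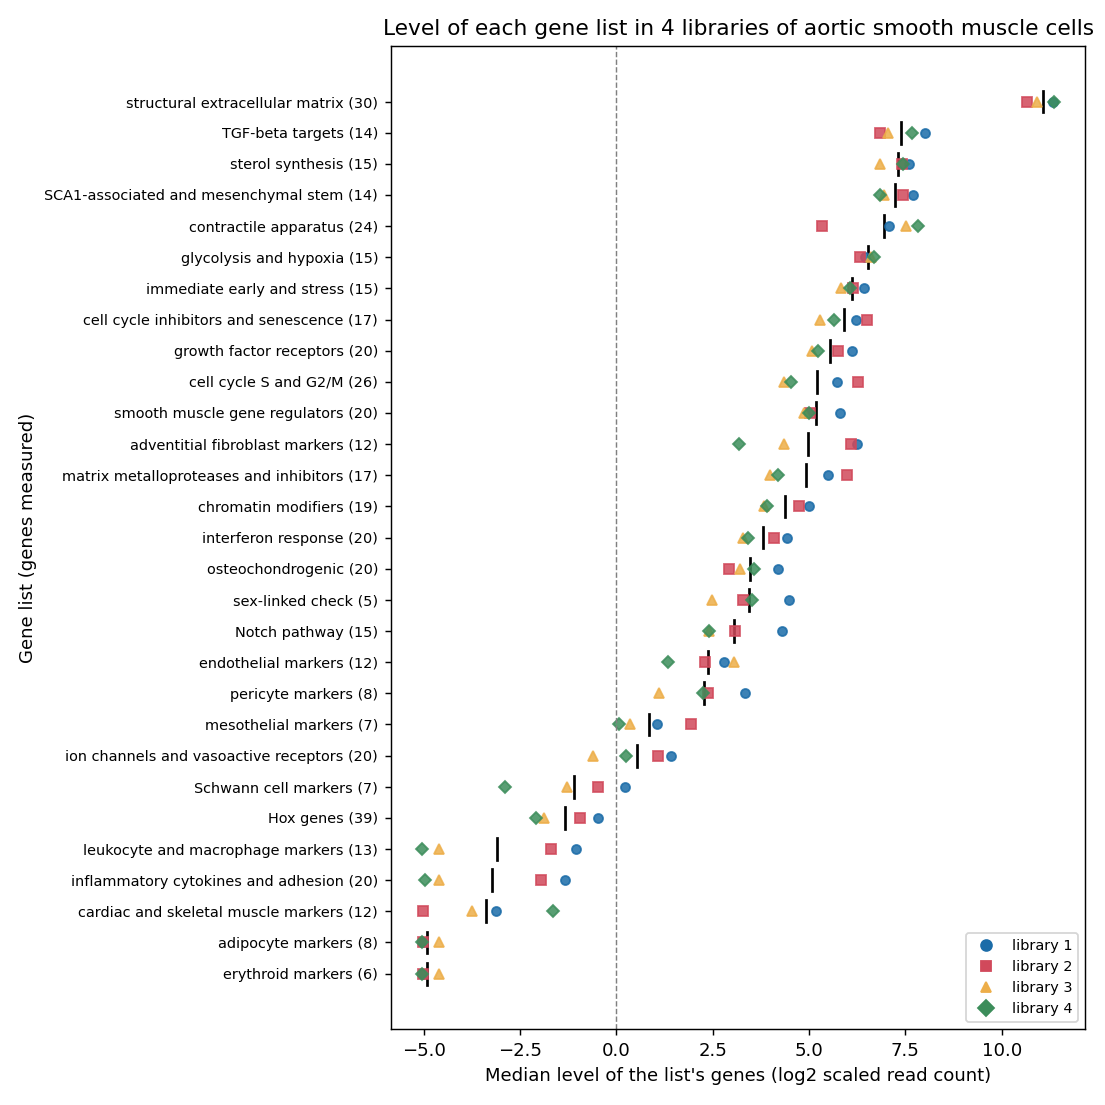
Median log2 scaled read count of each of 29 gene lists (horizontal axis) in each of the 4 libraries (symbols), with the mean over libraries as a vertical bar and the number of measured genes in brackets. Structural matrix genes lie highest at 11.06, and adipocyte and erythroid markers lie at the floor given to genes without reads.

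Genes of the structural extracellular matrix formed the highest of the 29 lists, with 29 of 30 genes detected and a median of 11.06 ± 0.34 (percentile 100). Besides the collagens and elastin, Fn1, encoding the adhesive glycoprotein fibronectin, averaged 13.53 ± 0.63, and Col3a1, the type III collagen gene, 11.38 ± 0.66. Matrix proteases were more divided, with 10 of 17 protease and inhibitor genes detected and a median of 4.92 ± 0.97 (percentile 63.3). The inhibitors Timp1, Timp2 and Timp3 averaged 12.50 ± 0.59, 12.58 ± 0.25 and 12.48 ± 0.34. Mmp2, a gelatinase, and Mmp14, a membrane-bound protease that activates it, averaged 10.60 ± 0.31 and 10.64 ± 0.19. The other gelatinase gene, Mmp9, had 7, 2, 11 and 8 reads. Mmp3, encoding stromelysin, had 785 and 2492 reads in libraries 1 and 2, against 13 and 6 in libraries 3 and 4, and Mmp8 had none.

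Most cytokine genes were near or below detection. Of 20 inflammatory and adhesion genes, 7 were detected, and the list median of -3.21 ± 1.83 lay below all random lists (percentile 0). This median contains genes without reads at their floor, and was -2.36 with those genes set at 3 reads, while the mean over the list's genes was -0.02 (percentile 0). The detected members included Csf1, the macrophage growth factor gene (10.57 ± 0.84), Cxcl12, a homeostatic chemokine gene (10.50 ± 0.80), and the adhesion molecule genes Icam1 (7.42 ± 0.92) and Vcam1 (7.33 ± 0.58). Il6 had 270 and 232 reads in libraries 1 and 2 and none in libraries 3 and 4. Il1a had at most 3 reads in a library and Il1b none. Interferon-response genes were low to moderate, with 14 of 20 detected and a median of 3.81 ± 0.55 (percentile 13.0). Their highest members were Bst2 (6.90 ± 0.11), the RNA sensor gene Ddx58 (6.03 ± 0.59), Ifit3 (5.81 ± 0.55) and Stat2 (5.41 ± 0.81), followed by Isg15 (4.68 ± 0.41), Ifit1 (4.57 ± 0.42) and Ifit2 (3.45 ± 1.03).

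Genes associated with SCA1-positive and mesenchymal stem cells were high, with 13 of 14 detected and a median of 7.23 ± 0.40 (percentile 99.93). Ly6a, which encodes SCA1, averaged 7.61 ± 0.75 (chromosome 15, 74994878 to 74997634), Cd34 7.54 ± 0.99, Thy1 9.09 ± 0.58, Cd248 9.61 ± 0.48 and Itgb1 10.66 ± 0.41. The related gene Ly6c1 averaged 5.26 ± 0.83; reads of the closely related Ly6 genes can be assigned to one another. Nes, the intermediate filament gene nestin, differed widely, with deposited values of 8.20, 10.22, 12.51 and 12.45. The osteochondrogenic list had 14 of 20 genes detected and a lower median of 3.48 ± 0.54 (percentile 5.98), but held Col2a1 and Comp, a cartilage matrix gene (10.82 ± 1.62). Spp1, encoding osteopontin, averaged 9.20 ± 2.04, Tnfrsf11b, encoding osteoprotegerin, 8.13 ± 1.06, and Sox9, the chondrocyte transcription factor gene, 6.20 ± 0.41. Of the bone transcription factors, Runx2 averaged 3.60 ± 0.49, and Sp7 had 35 and 13 reads in libraries 1 and 4 and none in the others.

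All 26 genes of the S and G2/M phases were detected, with a median of 5.22 ± 0.93 (percentile 81.4). Top2a averaged 7.82 ± 0.77, Mcm6 7.03 ± 0.55, E2f1 6.81 ± 0.73, the proliferation marker Mki67 6.53 ± 0.85 and Cdk1 4.74 ± 1.10. The inhibitor and senescence list had 17 of 17 genes detected and a median of 5.91 ± 0.55 (percentile 95.3). In it, Cdkn1a (p21) averaged 9.47 ± 0.12, Igfbp7 8.36 ± 0.78, Cdkn2a 7.50 ± 0.23, Cdkn1b 5.84 ± 0.34 and Cdkn1c 3.96 ± 0.73.

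Hox genes, which record position along the body axis, were detected mainly in the lower paralog groups, with 14 of 23 genes of groups up to 8 and 1 of 16 genes of groups from 9 up. Of 39 measured Hox genes, 15 were detected and 10 had no reads in any library, and the list median was -1.34 ± 0.76 (percentile 0). The detected genes were 5 of 11 in the Hoxa cluster, 7 of 10 in Hoxb, 0 of 9 in Hoxc and 3 of 9 in Hoxd. Among the genes reported here, Hoxb4 was highest at 5.36 ± 0.37 (chromosome 11, 96316684 to 96321638), followed by Hoxa3 (4.92 ± 0.10), Hoxb6 (4.55 ± 0.16), Hoxb5 (4.47 ± 0.18), Hoxa5 (4.40 ± 0.44), Hoxa2 (4.38 ± 0.07) and Hoxb2 (4.23 ± 0.40). Lower values included those of Hoxb3 (3.74 ± 0.26), Hoxb7 (3.53 ± 0.29), Hoxa4 (2.73 ± 0.51), Hoxd3 (1.74 ± 0.27), Hoxd8 (1.60 ± 0.49), Hoxd4 (1.54 ± 0.40) and Hoxb9 (0.72 ± 0.59). Hoxb9 was the detected gene of the higher groups.

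**Figure D2:**
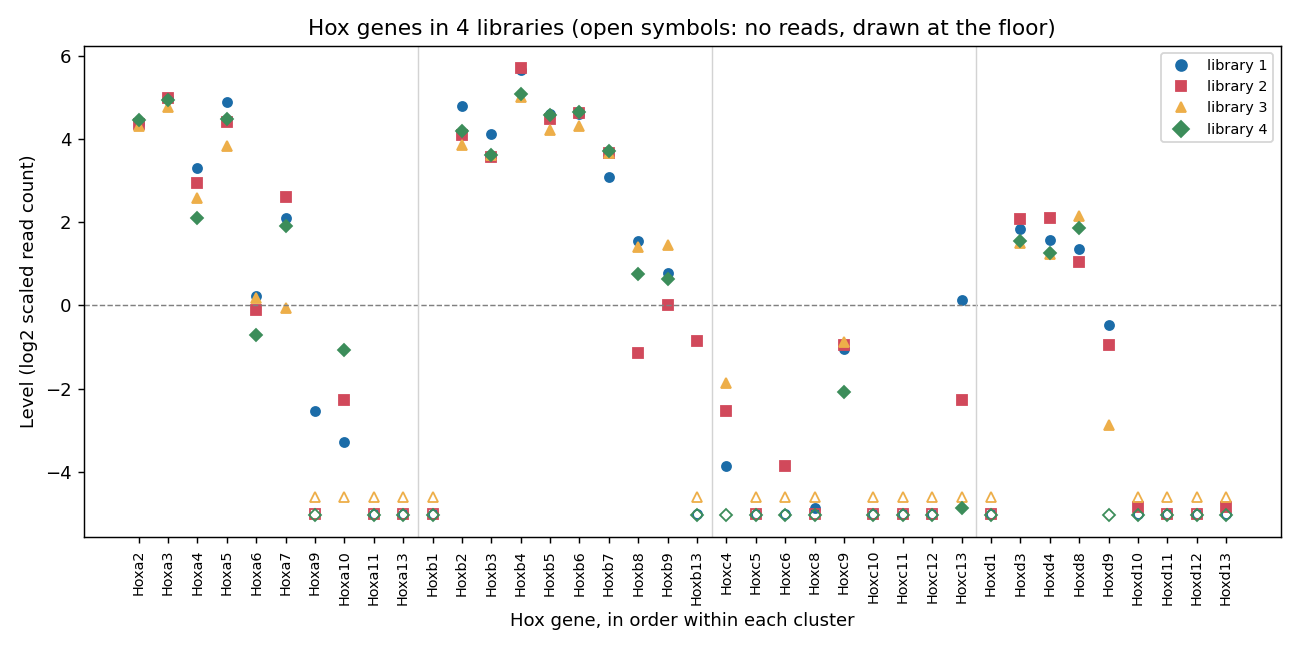
Log2 scaled read count (vertical axis) of Hox genes, ordered by number within the Hoxa, Hoxb, Hoxc and Hoxd clusters, in the 4 libraries (symbols), with open symbols for no reads and the detection threshold as a dashed line. The genes above the threshold in 4 of 4 libraries belong to the Hoxa, Hoxb and Hoxd clusters, with Hoxb4 highest at 5.36.

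Among growth factor receptor genes 17 of 20 were detected, with a median of 5.55 ± 0.48 (percentile 90.4). Axl averaged 9.80 ± 0.68, Pdgfrb, the receptor gene of the mural cell mitogen PDGF-BB, 9.52 ± 0.48, Fgfr1 8.74 ± 0.43, Igf1r 7.88 ± 0.20 and Pdgfra 5.92 ± 1.22. The Notch pathway had 10 of 15 genes detected and a median of 3.04 ± 0.90 (percentile 3.89), led by the transcription factor gene Rbpj (8.00 ± 0.39), Notch2 (6.88 ± 0.62), Jag1 (6.83 ± 0.94) and Hes1 (6.00 ± 0.32). Notch1 averaged 5.08 ± 0.41 and Notch3, a receptor characteristic of arterial smooth muscle in tissue, 4.30 ± 1.36. TGF-beta ligands and targets were high, with 13 of 14 detected and a median of 7.39 ± 0.54 (percentile 99.99). In this list Ctgf averaged 12.38 ± 0.58, Pmepa1 8.71 ± 0.51, Id1 8.31 ± 0.27, and the ligand genes Tgfb3, Tgfb2 and Tgfb1 7.98 ± 0.74, 7.01 ± 0.74 and 5.87 ± 0.52.

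Ion channel and vasoactive receptor genes were among the lowest of the smooth muscle lists, with 7 of 20 detected and a median of 0.54 ± 0.91 (percentile 0). The detected members included the calcium store genes Atp2a2 (8.56 ± 0.47), Stim1 (5.91 ± 0.61) and Orai1 (5.82 ± 0.51), and the adrenoceptor gene Adra1d (6.85 ± 0.39). Cacna1c, encoding the main L-type calcium channel of smooth muscle, had 336, 67, 52 and 0 reads. The T-type channel genes Cacna1g and Cacna1h had 327, 180, 29 and 17 reads, and 98, 45, 21 and 9 reads.

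Sterol synthesis genes were all detected (15 of 15), with a median of 7.32 ± 0.32 (percentile 99.98). Sqle averaged 9.25 ± 0.22, Fdps 8.29 ± 0.26, the master regulator gene Srebf2 8.06 ± 0.38 and Hmgcs1 7.76 ± 0.36. Glycolysis and hypoxia genes were also all detected (15 of 15), at a median of 6.52 ± 0.17 (percentile 99.1). Pkm averaged 12.85 ± 0.55, Aldoa 11.47 ± 0.37, Eno1 11.47 ± 0.25, Ldha 10.95 ± 0.40, Slc2a1 7.67 ± 0.89, Pfkp 6.40 ± 0.45 and Hk2 6.39 ± 0.17. Immediate early and stress genes had 15 of 15 detected and a median of 6.12 ± 0.24 (percentile 96.8), from Hmox1 (9.10 ± 0.28), Dusp1 (7.62 ± 0.17), Ier2 (7.45 ± 0.70), Ddit3 (7.14 ± 0.15) and Jun (7.12 ± 0.15) to Fos (1.36 ± 0.74) and Fosb (1.23 ± 0.36). Chromatin modifier genes had 16 of 19 detected and a median of 4.37 ± 0.59 (percentile 34.5). The histone methyltransferase genes Ehmt2, Ehmt1 and Setdb1 averaged 9.62 ± 0.29, 5.34 ± 0.60 and 4.43 ± 0.54, the remodeller gene Smarca4 8.04 ± 0.53, Kdm4a 7.40 ± 0.54 and Dnmt1 6.43 ± 0.78.

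Most lists of markers of other cell types had low medians, and the adventitial fibroblast list was an exception. Leukocyte markers had 2 of 13 genes detected, Csf1r (3.76 ± 0.64) and Lyz2 (2.74 ± 2.10), and a median of -3.09 ± 2.02 (percentile 0), or -2.23 with genes without reads set at 3 reads. Ptprc had 13, 27, 0 and 12 reads, C1qa 173, 201, 0 and 18, Cd68 49, 35, 42 and 21, and the macrophage gene Emr1 14, 4, 0 and 0. Endothelial markers had 8 of 12 detected at a median of 2.37 ± 0.76 (percentile 1.46). Erg averaged 6.44 ± 0.56, Egfl7 4.05 ± 0.63, Tie1 3.42 ± 0.80, Pecam1 2.95 ± 1.04 and Vwf 2.88 ± 0.53, and Cdh5 had 206, 78, 45 and 25 reads. Adventitial fibroblast markers had 11 of 12 detected at a median of 4.97 ± 1.46 (percentile 63.7). Gsn averaged 11.60 ± 0.08, Mfap5 7.02 ± 0.82, Serpinf1 6.46 ± 2.26, Dpt 4.60 ± 2.87 and Pi16 3.13 ± 1.10. Of the pericyte markers 4 of 8 were detected at a list median of 2.27 ± 0.92 (percentile 3.29), namely Cspg4 (9.54 ± 1.24), Rgs5 (7.77 ± 0.47), Mcam (5.71 ± 1.41) and Notch3, while Kcnj8 had 66, 56, 10 and 41 reads.

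Mesothelial markers had 4 of 7 genes detected and a median of 0.86 ± 0.83 (percentile 0.31), with Krt19 at 5.07 ± 0.71, Upk3b at 4.96 ± 0.80, Krt18 at 3.83 ± 1.65 and Msln at 0.86 ± 0.83, and Lrrn4 had 52, 33, 0 and 0 reads. Schwann cell markers had 2 of 7 detected, S100b (7.49 ± 1.04) and Ncam1 (5.42 ± 0.34), at a median of -1.10 ± 1.34 (percentile 0). The myelin gene Mbp had at most 34 reads in a library. Adipocyte markers had 2 of 8 detected, Fabp4 (3.70 ± 0.44) and Pparg (1.45 ± 0.80), with a median at the floor. Lep and Adipoq had 7 and 6 reads in a single library each, and Plin1 had none. Cardiac and skeletal muscle markers had 4 of 12 detected and a median of -3.38 ± 1.40 (percentile 0), or -2.53 with genes without reads at 3 reads. These were Tnnt2 (7.73 ± 0.77), Acta1 (5.69 ± 3.59), Tnni3 (2.91 ± 0.55) and Tnnt3 (2.15 ± 0.78). Myh7 had 16 reads and Actc1 5 reads in a single library, and Myh6 had none. None of the 6 erythroid markers was detected; Alas2 had at most 11 reads in a library, Hbb-b1 2, and Hbb-b2 and Hba-a1 none. The Y-linked genes Eif2s3y (5.95 ± 0.21), Ddx3y (5.29 ± 0.37), Kdm5d (3.44 ± 0.82) and Uty (2.23 ± 0.73) were detected in 4 of 4 libraries, and Xist, transcribed from the inactive X chromosome, had 0, 2, 2 and 10 reads.

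Within libraries, 22 prespecified differences between genes or lists were compared. Nonmuscle myosin genes lay above the smooth muscle form: Myh10 exceeded Myh11 by 2.59 ± 1.29 and Myh9 exceeded it by 5.92 ± 1.36. Pdgfrb exceeded Pdgfra by 3.59 ± 1.24, Col1a1 exceeded Col3a1 by 2.63 ± 0.47, Mmp2 exceeded Mmp9 by 12.79 ± 1.03, Spp1 exceeded Runx2 by 5.59 ± 1.75 and Ly6a exceeded Pecam1 by 4.66 ± 1.02. Notch3 minus Notch2 was -2.58 ± 0.92. Kcnn4, the intermediate-conductance potassium channel gene, had 93, 444, 672 and 1317 reads, against 2, 0, 0 and 0 for Kcnma1, the large-conductance channel gene of contractile smooth muscle. Pooled, the ratio of 2526 to 2 reads was 1263, with an exact binomial 95% interval of 349 to 10435 that covers counting error only and takes each counted read as independent. It does not cover the spread between libraries: both Kcnma1 reads were in library 1, where the ratio was 46.5, and without library 4 the pooled ratio was 604.5.

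Contractile genes lay below the structural matrix genes (difference of the list medians -4.11 ± 0.88) and above the osteochondrogenic (3.47 ± 0.97), endothelial (4.58 ± 1.43) and leukocyte lists (10.04 ± 2.89, or 9.17 with genes without reads at 3 reads). Matrix genes exceeded the protease and inhibitor list by 6.14 ± 1.15 and the adventitial fibroblast list by 6.09 ± 1.62, and cell cycle genes minus inhibitors gave -0.69 ± 0.40. The matrix and fibroblast lists share Dcn and Lum. Of the 22 differences, 19 had 1 sign in 4 of 4 libraries. For these the exact two-sided sign-flip permutation test gave p = 0.125, adjusted p = 0.145 over 22 tests (Benjamini-Hochberg), and 0.125 is the smallest p that 4 libraries allow, so none can pass a threshold of 0.05. The exceptions were Timp1 minus Timp3 (0.02 ± 0.88, exact p = 1), Fn1 minus Eln (-0.27 ± 1.52, exact p = 0.75) and Ednra minus Ednrb, the endothelin receptor genes, with 59, 69, 0 and 36 against 23, 24, 0 and 0 reads (exact p = 0.25). Acta2 minus Actb (-0.85 ± 0.66, near 0 in library 1) and Cdkn1a minus Cdkn2a (1.97 ± 0.32) had 1 sign as measured, but per exon length they were -0.56 and 0.37 and had that sign in 3 of 4 libraries, while Timp1 minus Timp3 became 3.21, positive in 4 of 4.

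**Figure D3:**
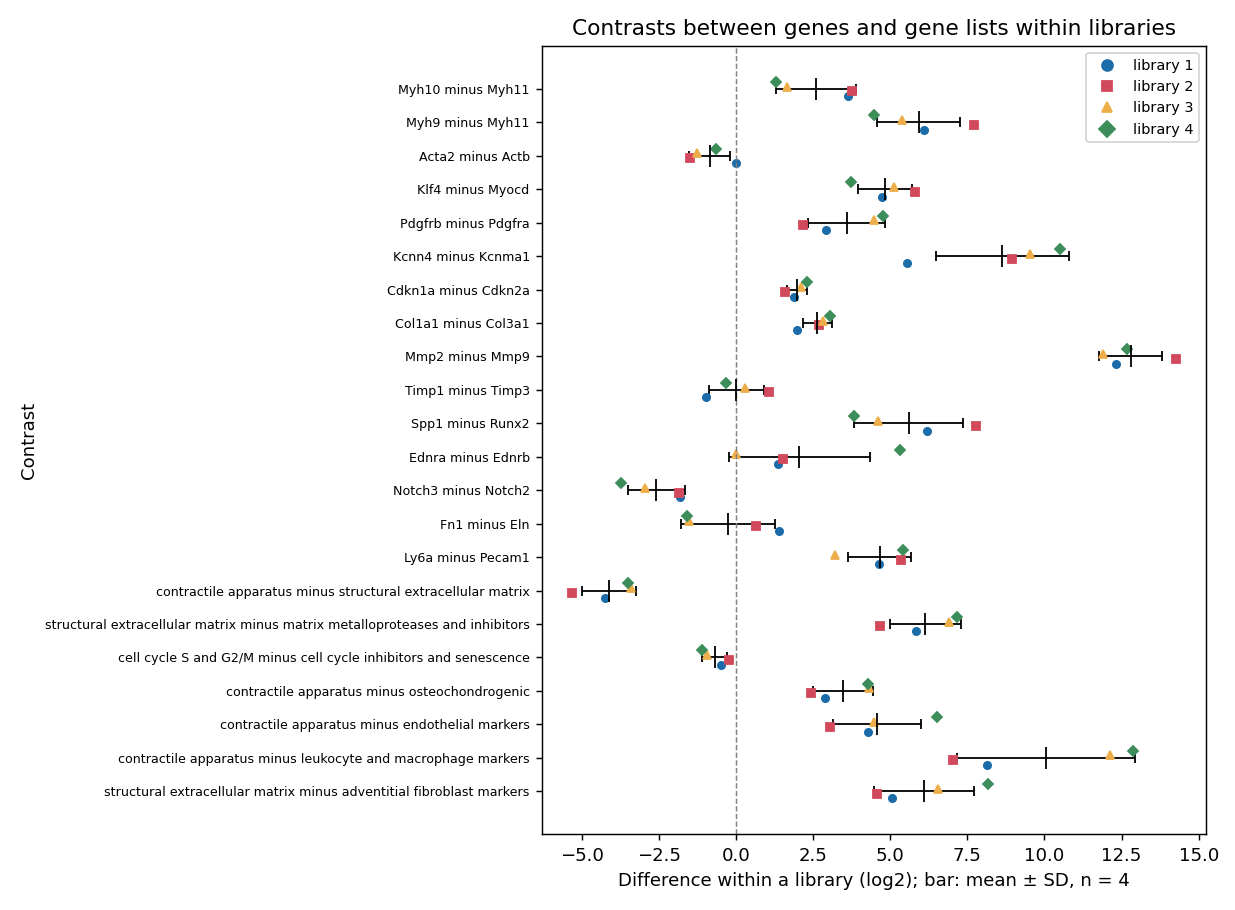
Differences in log2 level between genes or list medians within a library (horizontal axis) for the 22 fixed contrasts, with 1 symbol per library and bars of mean ± SD (n = 4). In 19 contrasts the 4 libraries lie on 1 side of 0, and Timp1 minus Timp3, Fn1 minus Eln and Ednra minus Ednrb are the exceptions.

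The libraries differed most in contractile, cell cycle and adventitial fibroblast genes. The labels do not say whether the libraries came from separate animals or cultures, so the spread between them may be partly technical. Median-ratio size factors were 0.32, 0.10, -0.30 and -0.12 on the log2 scale, a range of 0.62, and were subtracted from the libraries' values. The list means and gene values that follow are given after this scaling unless described as deposited. The 21 detected contractile genes averaged 7.49, 6.80, 8.68 and 8.99 in libraries 1 to 4, with 15 highest in library 4 and 18 lowest in library 2. Acta2 had values of 11.72, 10.66, 13.06 and 13.28, and Myh11 of 6.80, 5.24, 8.37 and 9.36. The cell cycle list averaged 5.41, 6.28, 4.49 and 4.77, and all 26 genes were highest in library 2 (25 of 26 without this scaling). Mki67 stood at 6.35, 7.57, 6.03 and 6.16. The 11 detected adventitial fibroblast markers averaged 6.50, 6.47, 4.93 and 4.19, and Dpt, encoding the matrix protein dermatopontin, stood at 6.83, 6.92, 2.62 and 2.04. Endothelial markers averaged 3.17, 3.03, 4.19 and 2.56, and all 8 detected genes were highest in library 3 (5 of 8 without this scaling).

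As deposited, the list mean of contractile genes had an SD of 0.85 between libraries against 0.16 in expression-matched random lists, that of cell cycle genes 0.99 against 0.29, and that of fibroblast markers 1.38 against 0.29 (percentile 100 for each). Of 21 lists with at least 5 detected genes, 13 lay above the central 95% of matched random lists, and 8 did so after median-ratio scaling, namely 7 of the 13 and the endothelial list (percentile 95.25 before and 99.94 after). As deposited, the endothelial list stood at percentile 27.63 without library 4, with an SD of 0.30 in place of 0.62. After scaling, its means in libraries 1 to 3 were 3.17, 3.03 and 4.19. Its scaled percentile without library 4 was not computed. The 6 lists lost after scaling were the matrix (percentile 100 to 70.07), protease (99.14 to 36.34), inflammatory (99.98 to 96.36), inhibitor (99.66 to 94.12), growth factor receptor (99.25 to 91.88) and sterol lists (98.47 to 66.40). When 1 library was left out in turn from the values as deposited, 5 of the 13 stayed above that range each time. Of these 5, the contractile, cell cycle, fibroblast and chromatin lists also stayed above it after scaling, and the inflammatory list did not. The other 8 did not: without library 1, Notch genes went from percentile 99.83 to 10.99, growth factor receptors from 99.25 to 38.05, matrix genes from 100 to 96.21 and proteases from 99.14 to 96.57. Without library 2, osteochondrogenic genes went from 99.15 to 67.12 and TGF-beta genes from 99.07 to 92.76, and without library 3, sterol genes went from 98.47 to 76.11 and inhibitor genes from 99.66 to 90.60. Glycolysis genes (percentile 0.95) and Hox genes (1.73) differed less than matched lists as deposited, but stood at percentiles 89.7 and 48.9 after median-ratio scaling.

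**Figure D4:**
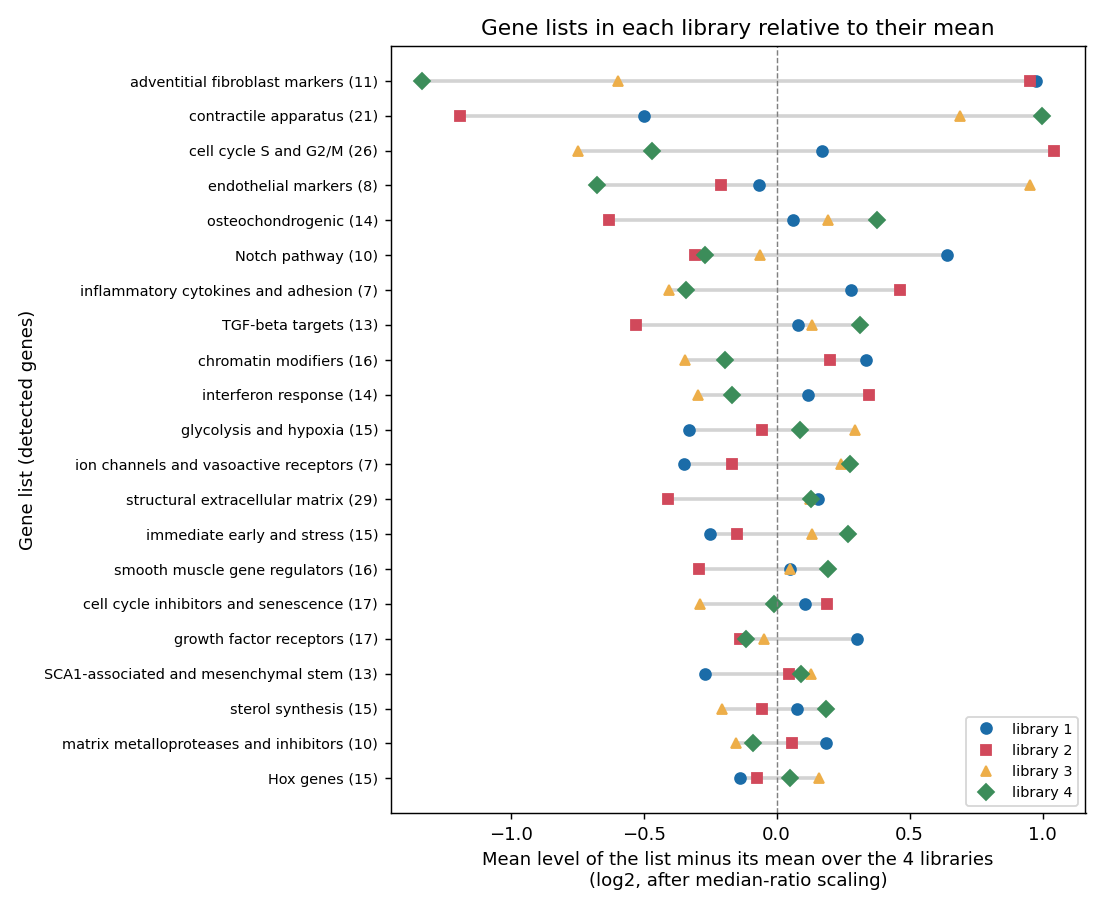
Mean level of each of 21 gene lists in each library (symbols) minus its mean over the 4 libraries, in log2 units after median-ratio scaling, with the number of detected genes in brackets. Fibroblast markers range from 6.50 in library 1 to 4.19 in library 4, and contractile genes from 6.80 in library 2 to 8.99 in library 4.

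Single genes with the largest SD included Acta1, the skeletal muscle actin gene, with scaled values of 2.47, 2.30, 8.74 and 9.26 (chromosome 8, 123891767 to 123894736). Its reads can be shared with other actin genes. Col4a3, a basement membrane collagen gene (3.39, 2.30, 7.38 and 7.23), Cytl1 (2.68, 0.05, 6.38 and 6.49) and Fhad1 (0.21, 0.96, 5.19 and 4.45) also had their highest values in libraries 3 and 4. Higher values in libraries 1 and 2 were found for Xdh, the xanthine dehydrogenase gene (7.18, 7.31, 1.92 and 2.96), Sfrp1, a Wnt antagonist gene (7.66, 7.17, 4.25 and 3.35), Serpinf1 (8.21, 8.19, 5.16 and 4.30), and Aldh1a2, a retinoic acid synthesis gene (5.42, 4.94, 1.26 and 1.35). Libraries 1 and 2 were also the higher ones for Abca8a (5.87, 4.79, 0.59 and 0.73), Nkd2 (5.44, 5.08, 0.92 and 0.37), Dpep1 (5.15, 4.97, 1.59 and 0.92), Hmha1 (4.09, 5.09, 0.64 and 0.20), Prkar2b (4.47, 4.80, 1.19 and 1.13) and Gda (3.87, 4.49, 0.79 and 0.67). Of the 12306 detected genes, 4978 (40.5%) had an SD above 0.5 as deposited and 714 (5.80%) an SD above 1, around a median SD of 0.43. After median-ratio scaling 3773 had an SD above 0.5. Exon length and GC content together accounted for 18.4% of the variance of the genes' deviations from their 4-library mean in library 1, against 1.66%, 7.34% and 2.82% in libraries 2 to 4. Spearman's rho of these deviations with exon length was 0.39 in library 1 and -0.14, -0.24 and -0.15 in the others. Length and GC correction left 3140 of 11789 genes above 0.5, against 4772 of them as deposited. The correction also removed each library's overall shift, so the drop cannot be assigned to length and GC alone. After this correction 9 of the 13 lists stayed above the central 95%, and the interferon (percentile 96.57 to 98.34) and endothelial lists (95.25 to 99.93) rose above it. The other 4 of the 13 did not stay above it. They were growth factor receptors (percentile 99.25 to 66.64), matrix genes (100 to 82.46), proteases (99.14 to 64.64) and sterol genes (98.47 to 79.24). These 4 were also lost after median-ratio scaling. Pearson's r across detected genes, which are not independent replicates, ran from 0.923 (libraries 1 and 3) to 0.980 (libraries 3 and 4). It was 0.964 for libraries 1 and 2, and 0.923 to 0.951 between either of them and library 3 or 4. The first principal component, the main axis of difference between libraries, held 65.6% of the variance of the deviations. On it libraries 1 and 2 (0.61 and 0.36) lay opposite libraries 3 and 4 (-0.58 and -0.39). The SD over 4 libraries thus includes the difference between these pairs.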

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

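The tests of sequencing depth, of adventitial fibroblasts and of reads shared between collagens were chosen after their results had been seen, while those of gene length and GC content and of a cartilage gene set were written before theirs.

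In 9 of 232 genes, lists or library measures tested on the values as deposited, 1 library stood far from the other 3, measured by its gap to the nearest as a share of the whole range; chance gives about 5% of such groups. After median-ratio scaling none of the 8 genes and lists among them stood apart by this measure, so the values below depend on the scaling. Col1a1 was lower in library 3 (13.52, against 14.14 to 14.22 in the others, gap share 0.894), and S100a4 higher in library 2 (13.43 against 12.88 to 12.93, 0.904). Tnfrsf11b was lower in library 2 (6.55 against 8.56 to 8.78, 0.899), and Tnnt2, a troponin gene, higher in library 3 (8.89 against 7.30 to 7.40, 0.932). Among Hox genes, Hoxb6 was lower in library 3 (4.32 against 4.61 to 4.65, 0.896), Hoxb3 higher in library 1 (4.12 against 3.58 to 3.63, 0.909) and Hoxb7 lower in library 1 (3.09 against 3.66 to 3.71, 0.922). The median of the smooth muscle gene regulators was higher in library 1 (5.80 against 4.88 to 5.02, 0.846). The scaled gap shares of these 8 ran from 0.481 (Hoxb6) to 0.816 (Tnfrsf11b). Library 3 also held fewer reads on genes, 40342561 against 55521915 to 56793195 in the others (0.923).

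The contractile, cell cycle and adventitial fibroblast lists differed between libraries more than matched random lists did. A correction for exon length and GC content kept 118% ± 2.46 (bootstrap SD) of the deposited spread of the contractile list mean. It kept 79.2% ± 1.29 of that of the cell cycle list and 88.4% ± 3.03 of that of the fibroblast list. The correction also removed each library's overall shift, so these shares include rescaling. In this order, the corrected SDs were 1.00, 0.79 and 1.22, near the 1.02, 0.79 and 1.15 of median-ratio scaling alone. The spread that remained argues against length and GC bias as the whole cause. Libraries 1, 2 and 4 had depths within 1.02 times of each other, yet held at least 79.2% ± 2.33 of the range of each list mean, as deposited or scaled, which argues against depth as the whole cause. A differing share of adventitial fibroblasts stayed open: the ranges of 10 markers had an SD of 0.383 times their median, but these were markers below 5 in their lowest library, a choice that depends on the change itself, so the test decides nothing. In library 2 minus library 1, contractile genes differed by -0.90 after scaling. Fibroblast markers differed by -0.0049 ± 0.13 after scaling, with 6 of 12 lower in library 2. As deposited they differed by -0.23 ± 0.13, with 9 of 12 lower. Dilution by fibroblasts would raise these markers in library 2, and no rise was seen on either scale. The size of such a rise depends on the share of fibroblasts in library 1, which was not measured. A rise within the spread was thus not excluded, and dilution between libraries 1 and 2 stayed open. Passage number and animal were not tested. Between libraries 1 and 2 and libraries 3 and 4 the contractile and fibroblast lists ran opposite ways, as dilution would give, but this was not tested. In libraries 1 to 4 the scaled contractile means were 7.49, 6.80, 8.68 and 8.99, and the fibroblast means 6.50, 6.47, 4.93 and 4.19.

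Col2a1 stood among the most abundant transcripts, at -0.41 log2 units relative to Col1a1. If its reads came from 6 other fibrillar collagen genes, its change between 2 libraries would lie within the range of theirs; it lay outside by more than 0.1 log2 units in 1 of 6 library pairs, in 3 of 6 with no margin, and in 4 of 6 when Col11a1, 3.76 log2 units below it, was left out. The outcome depended on these choices, all made after the values were seen. Between libraries 2 and 4 as deposited, Col2a1 rose from 12.88 to 14.06. Over the same pair Col1a1 stood at 14.14 and 14.16, Col1a2 at 13.31 and 13.23, and Col5a2 at 12.87 and 13.40. With the 4 of 6 pairs, these values argue against the collagens other than Col11a1 as the whole source of the Col2a1 reads. Col11a1 rose from 9.24 to 10.40. Reads shared with it, or sharing of only a part of the reads, cannot be told apart from Col2a1 transcription here. A cartilage-like set of transcripts remained a candidate explanation: 16 of 23 other measured cartilage genes were detected (69.6%, against 47.4% of all genes), among them Col11a1 (9.84), Wwp2 (9.83), Fmod (7.94), Col9a3 (7.04) and Col11a2 (6.55). Matn1, Matn3, Lect1, Ucma, Epyc, Cilp and Scrg1 were not detected. The 47.4% is over all genes, numbered models and RNA genes included, and 35 of 43 collagen genes were detected. The detected share by itself thus does not tell a cartilage-like set from wide expression of matrix genes. As deposited, Col2a1 stood at 13.80 and 13.67 in libraries 1 and 3, and Col11a1 at 9.90 and 9.80. Between the same libraries Col9a2 rose from 3.07 to 5.19, Col9a3 from 5.85 to 8.33 and Col11a2 from 5.55 to 7.77. The collagens of the set thus did not all follow Col2a1.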

How the results depend on the processing

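The chi-square test, the length and GC correction and the setting of genes without reads at 3 reads were chosen after the results had been seen. No paired analysis was possible because the libraries form a single group, and the planned pseudocount alternative was not run because the table is on a log scale.

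The number of detected genes stayed within 1.5 times its value under each setting (9990 to 14178). The number of variable genes did not: it was 10519 with no filter on low values, 714 with an SD above 1, 11925 by the chi-square test of recovered reads, and 3140 after length and GC correction, while leaving out 1 library gave 3354 to 5752. The first count adds genes near the floor, the second is a stricter limit by construction, and the chi-square test asks only for spread beyond counting error. The correction covered 11789 genes and also removed each library's overall shift, so its drop cannot be assigned to length and GC alone. Median-ratio scaling gave 3773 variable genes, and a detection threshold of 5 gave 3354. The lowest correlation between libraries (0.923) was 0.966 over all genes, which include those without reads, and 0.923 to 0.944 when 1 library was left out. The number of lists with a level above the central 95% of random lists was 6, and 14 against random lists from all genes, since those hold many genes without reads. For the same reason no list lay below that range in this setting, against 10 before it: osteochondrogenic genes stood at percentile 91.66 (5.98 before), interferon genes at 94.68 (13.01), Notch genes at 82.52 (3.89) and inflammatory genes at 15.42 (0), so low percentiles hold only among genes detected in at least 1 library. With the mean over a list's genes in place of the median 7 lists lay above the range and 12 below, and 12 of 29 levels moved by more than their SD, the inflammatory list from -3.21 to -0.02 and the regulators from 5.17 to 4.29 (percentile 76.46 to 41.83). The number of lists with high differences between libraries was 13, and 8 with median-ratio scaling; the cause was not tested. The contractile, cell cycle and fibroblast lists stayed at percentile 100 in each setting run, but the SD of the contractile list mean (0.85) was 0.53 without library 2 and 1.03 without library 1.

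Of the contrasts, 2 changed sign without a library. Timp1 minus Timp3 ran from -0.34 (without library 2) to 0.35 when 1 library was left out, with -0.08 without library 3. Fn1 minus Eln ran from -0.82 to 0.17, and was 0.16 without library 3 and 0.17 without library 4. The other 20 kept their direction. Depth limited genes such as Kcnma1, Mmp9 and Ednrb, which had at most 24 reads in a library.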

Other observations

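The test of mitochondrial RNA was chosen after its result had been seen, and the gene families were chosen after the data were seen.

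Collagen genes were widely expressed, with 35 of 43 measured genes detected. Besides the fibrillar collagens, the basement membrane genes Col4a1 and Col4a2 averaged 12.45 ± 0.22 and 12.31 ± 0.37, and Col6a1 and Col6a2, of the beaded filament collagen, 11.97 ± 0.59 and 11.28 ± 0.51. Col28a1 stood at 8.74, 7.70, 5.09 and 4.65 in libraries 1 to 4 as deposited, and Col4a4 at 4.21, 2.75, 6.26 and 6.84. Of 7 insulin-like growth factor binding protein genes 6 were detected, led by Igfbp2 (13.00 ± 1.23) and Igfbp4 (10.20 ± 0.08), and Igfbp1 had no reads. The 81 detected genes of cytosolic ribosomal proteins averaged 9.06, 9.41, 9.22 and 9.29 in libraries 1 to 4 as deposited, with the highest in library 2, and 8.74, 9.31, 9.52 and 9.41 after median-ratio scaling, with the highest in library 3.

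In library 3, mt-Nd4, a mitochondrial gene of respiratory complex I, stood at a deposited value of 11.61, against 5.40, 6.99 and 7.37 in libraries 1, 2 and 4, an excess of 5.02 log2 units over their mean. It was hypothesised that library 3 held more mitochondrial RNA. The other 12 mitochondrial protein genes had a median excess of 1.15 (SD 0.81), from -0.05 for mt-Co2 to 2.60 for mt-Nd5, which is too small to account for mt-Nd4 as a whole. Its cause stayed open, and no biological explanation was tested.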
